A study of Mus musculus with 12 samples.

How the data were processed

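Total RNA of 12 samples of sorted and infected mouse mammary epithelial cells had been extracted with the RNeasy micro kit, turned into biotinylated cRNA with the Ambion MessageAmp kit and hybridized to Illumina mouse whole-genome bead arrays. Groups were taken from the sample titles, population and virus labels: MaSC control, MaSC cre, luminal control and luminal cre, 3 arrays each. The titles call the cre samples a knock-down and other labels call them KO, and what T stands for in the genotype Ezh2T/+ F/F is not given in the sources used here. The labels number the animal pools 1 to 3 and give each pool to 1 array of every group, so control and cre arrays of a pool come from the same pooled animals. In MaSC, the replicate numbers 1 and 2 of the titles belong to pools 2 and 1, and pools were matched by the pool label.

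The deposited raw table holds 1 linear probe signal (intensity) per array, summarised with GenomeStudio 1.1.1 and neither background-corrected nor normalized. Beside each signal the deposited table holds a fraction that the file headers call a detection p value, but it is 1 for bright probes and lower for dim ones, so it was read as 1 minus the p-value. The processed values made by the authors are on a log2 scale and share their quantiles between arrays. The authors' notes name R 2.11.0 and limma 3.4.0 without assigning steps to them. The raw signals, corrected here as described next, came within 0.0192 log2 units of the authors' values on every probe and array.

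In R 4.3.3 with limma 3.58.1, signals were corrected and normalized with neqc (background from detection p-values, offset 16, quantile normalization, log2). A probe was tested when its detection p was under 0.01 on at least 3 of the 12 arrays, which kept 17036 of 45281 probes. Gene symbols came from the platform annotation and were brought up to date through Entrez identifiers, of which 99.7% were found. There were 34885 probes with 1 symbol, 18 with several and 10378 with none, and 2260 of the tested probes had no single symbol. Such probes were counted but not named. A gene was represented by its tested probe with the highest mean log2 value, which gave 9586 genes, and other probes of a named gene are given where they disagree in call, or in direction beyond values near 0. A probe with a detection p of 0.05 or more on every array of a group was taken as not above background there, and its fold is given as a bound.

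A mean per group was fitted to all 12 arrays with lmFit, followed by eBayes (prior degrees of freedom 3.50, residual 8), and adjusted p-values are Benjamini-Hochberg values of limma's moderated test with a threshold of 0.05. The 5 comparisons were cre against control in MaSC, cre against control in luminal cells, the mean of both, their difference (luminal minus MaSC) and luminal against MaSC in control arrays. All were two-sided. The design, the lists and most alternatives were fixed before the data were examined, and those added later are named as such. Because the pools are shared, the pairing was checked: after subtracting each group's mean, control and cre deviations of a pool correlated between 0.242 and 0.615 within a population (6 pairs). Across populations, deviations of a pool correlated between 0.104 and 0.345 (12 pairs). The means for different pools were -0.240 and -0.111. Subtracting the group means forces these below 0 where those of 1 pool lie above it, so they add no contrast of their own. The main fit leaves the pairing out. The counts of every comparison, and many of the named genes and lists, are therefore also given with the animal pool as a block. The consensus correlation of arrays of 1 pool was 0.222.

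Named were Ezh2, Ezh1, Eed and Suz12; per comparison the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with 1 direction in all 3 pools, leaving out clone and predicted names; and per list and comparison up to 4 members that passed and up to 2 bright ones that did not. The same rule was applied to the mean effect and to the blocked fit after their values had been seen. Other list members are given as the ones with the smallest p-values in their list, also chosen after their values were seen.

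The 29 lists covered PRC2, PRC1, cyclin-dependent kinase inhibitors, Hox genes, developmental factors silenced by Polycomb, imprinted genes, basal, hormone-sensing, luminal progenitor and general luminal markers, milk genes, both cell cycle phases, p53 targets, interferon response, mesenchymal, Wnt, Notch, immediate early and heat shock, endoplasmic reticulum stress, cholesterol synthesis, germline, fibroblast, endothelial, leukocyte, adipocyte, erythroid, housekeeping and other histone methylation genes. The 24 lists with at least 5 tested genes were tested with camera (preset correlation 0.01) and adjusted over lists within a comparison. For each comparison camera was repeated with an estimated correlation, and fry was run beside it. Lists share members, such as Ltf in the luminal progenitor and milk lists, Cdkn1c in the imprinted and kinase inhibitor lists and Lox in the fibroblast and mesenchymal lists. For every list called, the median, the mean and the test had 1 sign. Among lists without a call they differed in sign for PRC1, Wnt, immediate early and Hox genes in MaSC, and for Hox and other histone methylation genes in luminal cells. For the mean effect they differed for PRC1, Hox and general luminal genes, and between the populations for kinase inhibitors, imprinted genes and developmental factors. For the difference of effects they differed for PRC1, kinase inhibitors, developmental factors, basal markers and other histone methylation genes.

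The procedure was tested on simulated data with 17036 probes of which 200 were changed, beside a list of 30 probes shifted by 0.5 log2 units. A pool effect common to both populations held a share of 0.2 of the variance. In the real arrays the deviations of a pool correlated at a mean of 0.488 within and 0.222 across populations. The rates below therefore need not carry over to the real arrays. It recovered 22.4% of 1.5-fold, 70.1% of 2-fold and 92.4% of 4-fold changes in MaSC, 16.4%, 61.2% and 97.0% in luminal cells, 44.8%, 88.1% and 97.0% for the mean effect and 4.48%, 23.9% and 83.3% for the difference of effects, with 0.820% to 4.03% false calls among those made. With the pool block the false calls were 3.08% to 7.41%, above the threshold of 5% for the mean effect (6.42%) and for luminal against MaSC (7.41%). Each rate rests on 1 simulated data set per comparison. The spread of the rates was therefore not measured, and a true excess over 5% is not shown.

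Alternatives tried were other background corrections (offset 50, normexp without detection p-values), median scaling and cyclic loess, the authors' values, other filters on dim probes, the pool as a fixed or random block or by population, array quality weights, an intensity trend, fits to the compared groups alone, probes averaged per gene, an adjusted p under 0.10, and leaving out each array or pool. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The slide and position of each array are not given in the sources used here, so no test of array batches was made. No array was left out of the main comparisons, and every value column of the files was used.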

Results

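Transcripts were measured on 12 Illumina mouse bead arrays, 1 per sample of sorted mouse mammary epithelial cells. Cells of 8-week-old mice of the labelled genotype Ezh2T/+ F/F had been sorted into a fraction enriched for mammary stem cells (MaSC, CD29hiCD24+) and a luminal fraction (CD29loCD24+). They were infected outside the body with a virus expressing cre recombinase or with a control virus and sorted again for GFP. Cre removes DNA between its target sites, and the stated purpose was to find genes downstream of Ezh2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2). The 4 groups were MaSC control, MaSC cre, luminal control and luminal cre, with 3 arrays each, and each of 3 animal pools gave 1 array to every group. Between 15039 and 16170 of the 45281 probes had a detection p under 0.01 on an array, and the median raw signal per array lay between 102.7 and 150.9. The first principal component held 68.8% of the variance and separated the MaSC from the luminal arrays. The number of arrays limits the precision: every p-value below rests on 3 arrays per group.

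Ezh2 itself was reported first, as a check on the labels. Its brighter probe (ILMN_1234171) had a mean log2 signal of 9.85 ± 0.14 (SD, n = 3) in MaSC control arrays and 9.30 ± 0.25 in MaSC cre arrays, a log2 fold change of -0.55 ± 0.19 (SE) with an adjusted p of 0.302. In luminal cells the same probe stood at 9.04 ± 0.33 in control and 8.74 ± 0.17 in cre arrays, a log2 fold change of -0.31 ± 0.19 with an adjusted p of 0.769. The signal was lower with cre in 3 of 3 pools of MaSC and in 2 of 3 pools of luminal cells. With the animal pool as a block the adjusted p of Ezh2 was 0.198 in MaSC and 0.583 in luminal cells. A dimmer Ezh2 probe (ILMN_2988572) had log2 fold changes of -0.70 ± 0.19 in MaSC and -0.73 ± 0.19 in luminal cells, with adjusted p of 0.191 and 0.229. It was not above background on any luminal cre array, so the luminal value is a fall of at least 1.21-fold. Averaged over both populations this dimmer probe was lower with cre (adjusted p = 0.0317, 0.0155 with the pool block), by an amount left open because of the luminal cre arrays, while the brighter probe had a mean log2 fold change of -0.43 (adjusted p = 0.137). A further Ezh2 probe was undetected on all 12 arrays, and whether any of the probes lies in the excised part of the gene is not known from the labels. Among the PRC2 partners, Suz12 had log2 fold changes of -0.34 in MaSC and -0.35 in luminal cells and Eed -0.12 and -0.20, none of them past the threshold. Ezh1 was not among the tested genes.

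**Figure D1:**
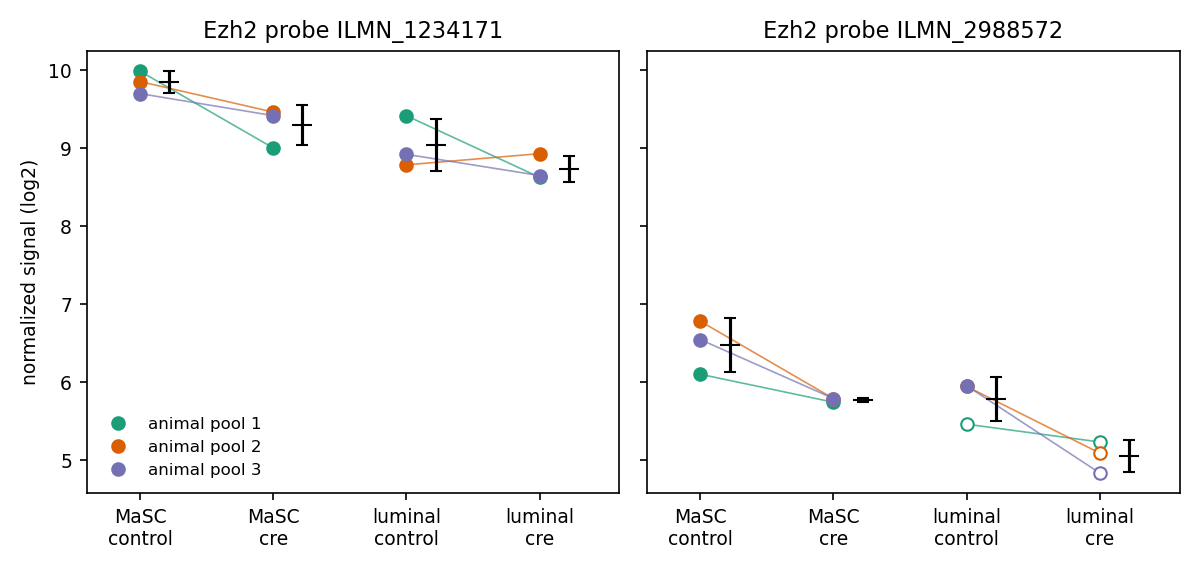
Normalized log2 signal (vertical axis) of the 2 detected Ezh2 probes on each of the 12 arrays by group (horizontal axis), with points coloured by animal pool, open where the detection p is 0.05 or more, lines joining control and cre of a pool, and bars for the mean ± SD of 3 arrays. The dimmer probe is lower with cre in all 3 pools of MaSC, its luminal cre points are all open, and the brighter probe rises in pool 2 of the luminal cells.

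In MaSC-enriched cells, cre raised 9 genes and lowered 4 of 9586 tested in the fit without the pool block (71 and 18 with it). The genes that rose included Crct1, a gene of the epidermal differentiation complex (2.49-fold, log2 fold change 1.32 ± 0.17, SE), Sprr1a, a precursor of the cornified envelope (2.25-fold, 1.17 ± 0.15), and Scel, which encodes sciellin of the same envelope (1.88-fold, 0.91 ± 0.14). The others were Svop, a synaptic vesicle transporter homologue that was not above background in MaSC control arrays (at least 2.43-fold higher), and Rgs17, a regulator of G protein signalling (2.74-fold). Also higher were Arsj, an arylsulfatase (2.32-fold), the ephrin ligand Efna3 (1.97-fold), the tyrosine kinase Tec (1.93-fold) and the glycosyltransferase Mgat4a (1.82-fold). Shcbp1, whose product acts in cytokinesis, fell by 1.09 on the log2 scale (SE 0.15). The secreted glycoprotein Reln fell by 0.95, the dynein chain Dnali1 by 0.77 and the RNA exonuclease Rexo5 by 0.75. All of these moved the same way in 3 of 3 pools, and their adjusted p lay between 0.0383 and 0.0497. A second Rgs17 probe had a log2 fold change of 1.21 with an adjusted p of 0.0501 (0.0347 with the pool block).

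Gene lists fixed beforehand moved together in MaSC. Of 24 lists tested, 10 were called by camera. Genes of G2 and mitosis fell as a group, with 29 of 30 members lower and a median log2 fold change of -0.50 (camera adjusted p = 2.08e-16, a call lost at 0.209 with an estimated correlation). No member passed over all probes, while 13 fell when adjusted over the list alone, among them Ect2 (-0.99), Ndc80 (-0.63) and Aurka (-0.64), of which Ect2 and Ndc80 passed over all probes with the pool block. Genes of G1/S and DNA replication fell likewise (median -0.43, 33 of 33 lower, adjusted p = 1.83e-14, also lost at 0.209 with an estimated correlation), with 3 past the threshold adjusted over the list alone, E2f1, Rpa2 and Mcm5. PRC2 subunits fell as a group (median -0.27, 8 of 8 lower, adjusted p = 1.60e-04, and 0.0352 with an estimated correlation), with Phf19, Ezh2 and Suz12 past the threshold adjusted over the list alone. Targets of p53 rose (median 0.28, 21 of 25 higher, adjusted p = 4.48e-05, and 0.0352 with an estimated correlation), with Trp53inp1 (0.75) and Ccng1 (0.46) past the threshold adjusted over the list alone.

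Markers of luminal progenitors and alveolar cells rose in MaSC with cre (median 0.43, 19 of 20 higher, adjusted p = 1.38e-04, a call lost at 0.209 with an estimated correlation), as did milk protein and lipid genes (median 0.45, 9 of 11 higher, adjusted p = 0.0104, likewise lost at 0.209 with an estimated correlation). Ltf, the milk and defence protein lactoferrin, led both lists at 1.93 ± 0.34 (adjusted p = 0.0594, and 0.00244 adjusted over the list alone for the progenitor list), followed by Notch3 (0.67) and Lcn2 (0.89). Imprinted genes rose (median 0.21, 16 of 19 higher, adjusted p = 0.0178, lost at 0.209 with an estimated correlation), with the cell cycle inhibitor Cdkn1c (1.16), Igf2 (1.78) and Slc22a18 (1.04) past the threshold adjusted over the list alone. Interferon response genes rose (median 0.33, adjusted p = 1.38e-04, but 0.511 with an estimated correlation). Cholesterol synthesis genes fell (median -0.15, adjusted p = 0.0151, but 0.671 with an estimated correlation). Neither list had a member past either threshold. Fibroblast markers also rose beside these groups (median 0.57, 11 of 12 higher, adjusted p = 0.0455, but 0.579 with an estimated correlation), with Lox at 0.75 and Col1a1 at 0.80. Of the lists too short to test, the leukocyte list (3 genes) had a median of 0.44, led by Ccl5 (1.30, adjusted p = 0.196). The adipocyte list (4 genes) had a median of 0.21 with Lep at 1.53 (adjusted p = 0.301), and the endothelial and germline lists (4 genes each) medians of 0.18. Adjusted over the list alone, Ccl5 and Lep rose and the endothelial gene Esam (-0.44) fell.

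The 14 lists without a call in MaSC had camera adjusted p between 0.0828 and 0.946. Developmental transcription factors that Polycomb silences in stem cells had a median log2 fold change of 0.0020 over 22 tested genes, with 11 higher and 11 lower, and Hox genes 0.056 over 10. These were 22 of 121 listed factors and 10 of 39 listed Hox genes. The others were detected on too few arrays or had no named probe, so the medians here and below do not cover silent members. Cyclin-dependent kinase inhibitors had a median of 0.26, of which Cdkn1c (1.16) and Cdkn2a (1.47) passed when adjusted over the list alone. Likewise adjusted over the list alone, Hoxb2 fell (-0.58) and the hormone-sensing markers Sytl2 (0.84) and Wnt5a (0.76), Notch3 and the immediate early gene Egr3 (0.86) rose. The remaining medians were -0.016 for PRC1 subunits, -0.041 for basal and myoepithelial markers, 0.26 for hormone-sensing luminal markers, 0.033 for general luminal genes, and 0.30 for mesenchymal genes. They were -0.015 for Wnt, 0.10 for Notch, -0.0017 for immediate early and heat shock, -0.13 for endoplasmic reticulum stress, -0.037 for housekeeping and -0.070 for other histone methylation genes.

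Counted by probe, 12 of 17036 rose and 7 fell in MaSC. With the animal pool as a block, 112 rose and 32 fell (71 and 18 genes). Of the genes added there, picked for naming after their values were seen, Ltf (1.93, blocked adjusted p = 0.0179), Ivl (1.43, 0.0263), S100a9 (1.35, 0.0302), Cdkn2a (1.47, 0.0421), Cdkn1c (1.16, 0.0263) and Ccl5 (1.30, 0.0251) rose. Atad2 (-1.36, 0.0459), Ect2 (-0.99, 0.0309) and Smc4 (-0.93, 0.0459) fell. A second Smc4 probe (-0.64, blocked adjusted p = 0.264) did not pass. All 10 list calls held in the blocked fit with the preset correlation, whereas PRC2 and p53 lost theirs there with an estimated correlation (adjusted p = 0.191). Leaving out any 1 of the 12 arrays left between 1 and 10 changed probes.

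In luminal cells, cre raised 2 genes and lowered 3 in the fit without the pool block (15 and 53 with it). Crct1 rose here too, from a signal not above background in luminal control arrays (at least 2.71-fold higher, log2 fold change 1.81 ± 0.17, adjusted p = 0.00206), and Bmp4, a secreted bone morphogenetic protein, rose 2.70-fold (1.43 ± 0.11, adjusted p = 3.27e-04). Ndc80, an outer kinetochore protein, fell by 1.23 (SE 0.14, adjusted p = 0.0077), Sgo2a, which protects centromeric cohesin, by 0.95 (SE 0.13, adjusted p = 0.0374), and Oip5, needed to load the centromeric histone, by 0.85 (SE 0.12, adjusted p = 0.0430). Each moved the same way in 3 of 3 pools, and a second Oip5 probe had a log2 fold change of -0.70 with an adjusted p of 0.154.

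Of the 24 lists, 6 were called in luminal cells. G2 and mitosis genes fell (median -0.79, 30 of 30 lower, camera adjusted p = 3.23e-33, a call lost at 0.0907 with an estimated correlation), 1 of them over all probes and 27 adjusted over the list alone (8 with the pool block over all probes), among them Cdk1 (-0.82), Aurkb (-0.85) and Nusap1 (-0.98). G1/S and replication genes fell (median -0.63, 33 of 33 lower, adjusted p = 1.59e-28, a call lost at 0.0988 with an estimated correlation), none over all probes and 25 adjusted over the list alone (5 with the pool block over all probes), led by Tk1 (-0.95), Rfc5 (-0.75) and Gins1 (-0.89). Targets of p53 rose (median 0.24, 20 of 25 higher, adjusted p = 1.07e-04, and 0.0529 with an estimated correlation), with Sesn2 (0.57), Dcxr (0.64), Phlda3 (0.49), Cdkn1a (0.50) and Mdm2 (0.42) past the threshold adjusted over the list alone. PRC2 subunits fell (median -0.26, 7 of 8 lower, adjusted p = 0.00376, and 0.0907 with an estimated correlation), with Phf19 (-0.72) and Suz12 (-0.35) past the threshold adjusted over the list alone. Interferon response genes (median 0.20, adjusted p = 0.0254, 0.684 with an estimated correlation) and mesenchymal genes (median 0.27, adjusted p = 0.0479, 0.597 with an estimated correlation) rose without a member past either threshold.

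Fibroblast markers had a median of 0.37 in luminal cre against control arrays (10 of 12 higher, adjusted p = 0.238), leukocyte markers 0.37 over 3 genes, adipocyte markers 0.048 and endothelial markers -0.023 over 4 genes each, and germline genes 0.069 over 4. Polycomb-silenced developmental factors had a median of 0.14 (16 of 22 higher, adjusted p = 0.290) and Hox genes 0.068. Adjusted over the list alone, Notch3 (0.78), Ltf (1.52), Cdkn1a (0.50), Cdkn1c (0.61) and Sesn2 (0.57) rose within lists that had no call. The other lists without a call had medians of 0.015 for PRC1, 0.33 for kinase inhibitors, 0.14 for imprinted genes, -0.033 for basal markers, 0.14 for hormone-sensing markers, 0.11 for luminal progenitor markers and -0.013 for general luminal genes. Medians were 0.18 for milk genes, 0.14 for Wnt, 0.16 for Notch, 0.085 for immediate early, -0.058 for endoplasmic reticulum stress, -0.091 for cholesterol, -0.033 for housekeeping and 0.060 for other histone methylation genes. By probe, 2 rose and 5 fell. With the animal pool as a block, 21 rose and 78 fell (15 and 53 genes). The genes added, picked for naming after their values were seen, included Ltf (1.52, blocked adjusted p = 0.0209), Kcnj15 (1.19, 0.0424) and Notch3 (0.78, 0.0441) among those that rose and Cep55 (-1.29, 0.0175), Pclaf (-1.18, 0.0138), Rrm2 (-1.12, 0.0441) and Mcm3 (-1.11, 0.0441) among those that fell. Second probes of Kcnj15 (0.99, blocked adjusted p = 0.0824), Cep55 (-0.50, 0.452) and Rrm2 (-0.92, 0.0563) did not pass with the block. Without luminal control replicate 1, 66 probes changed, and without any other single array between 3 and 6.

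**Figure D2:**
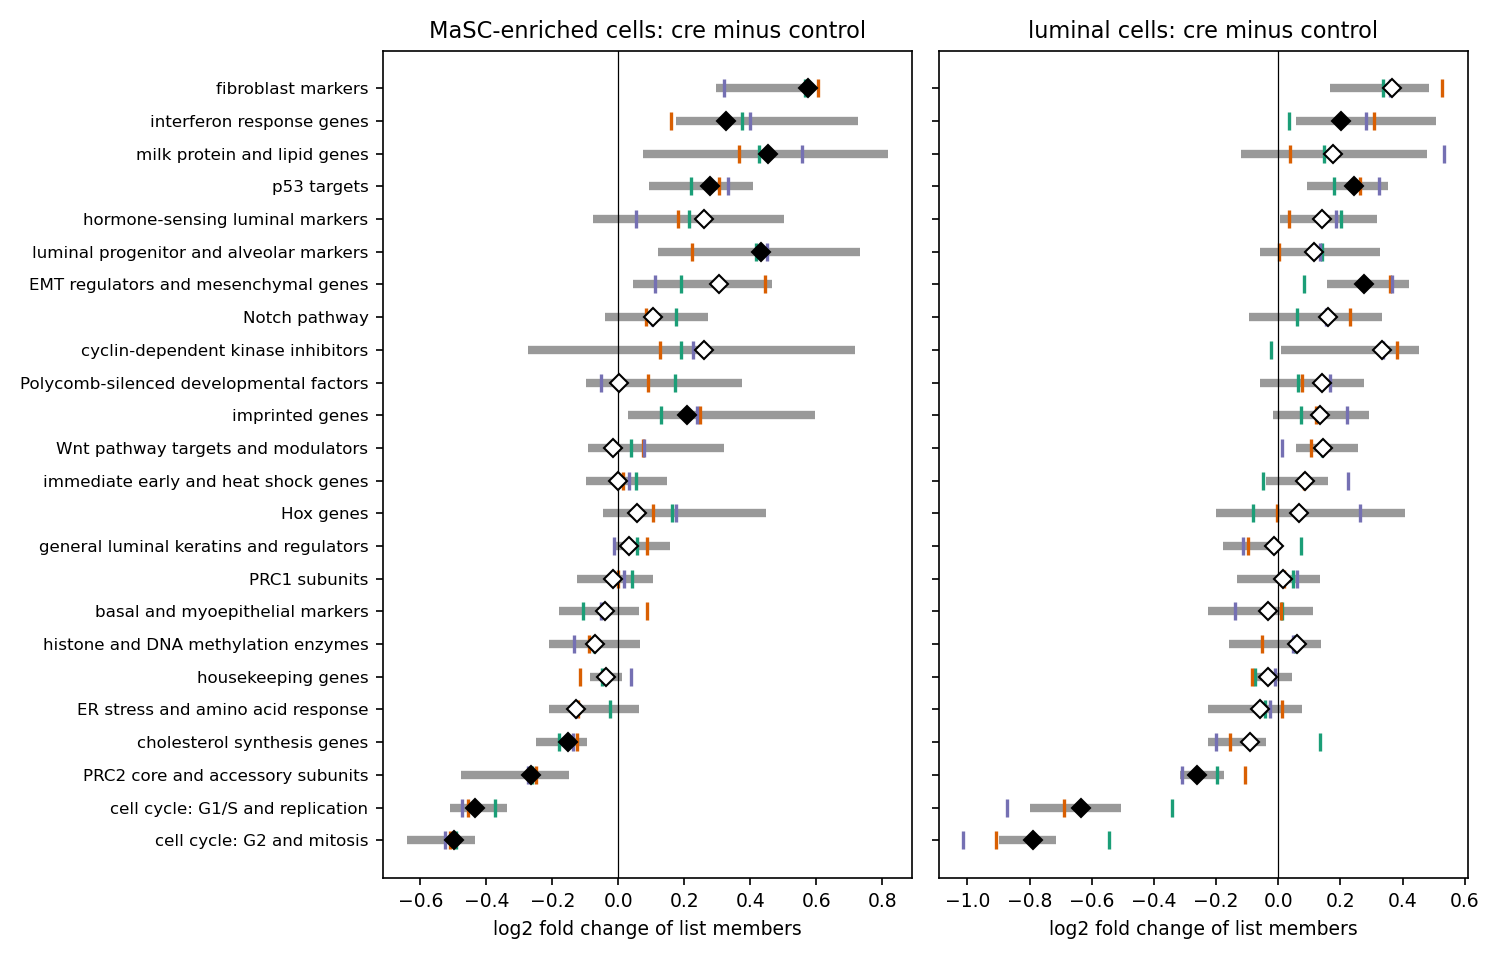
Log2 fold change of cre against control (horizontal axis) of the members of 24 gene lists (vertical axis) in MaSC-enriched and luminal cells, with diamonds at the list median, filled where the camera adjusted p with the preset correlation is under 0.05, grey bars over the quartiles and coloured ticks at the median in each animal pool. Both cell cycle lists lie lowest in both populations, at -0.50 and -0.43 in MaSC and -0.79 and -0.63 in luminal cells.

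Averaged over both populations, cre raised 60 genes and lowered 105 in the fit without the pool block (234 and 257 with it). The genes that rose most, picked for naming after their values were seen, included the growth factor Igf2 (3.44-fold, log2 fold change 1.78 ± 0.34, adjusted p = 0.0317) and Ltf (3.30-fold, 1.72 ± 0.24, adjusted p = 0.0174). Next came the potassium channel gene Kcnj15 (1.17), the surface protein Ly6d (1.12), Cdkn1c (0.88), the phospholipase Liph (0.88) and Lynx1 (0.87). For 11 of the 165 genes some group was not above background on any array, so that the size of their mean effect is left open. Among these were Crct1 (adjusted p = 3.67e-04), Svop (adjusted p = 0.0177), Bmp4 (adjusted p = 5.71e-04), which was above background in luminal cells only, and Cxcl10. The genes that fell most were Spsb4 (-1.14), the helicase subunit Mcm3 (-0.95), the cohesin acetyltransferase Esco2 (-0.93) and the kinesins Kif15 (-0.93) and Kif18a (-0.88). With them fell Ndc80 (-0.93), Spag5 (-0.91), Shcbp1 (-0.89), the ubiquitin ligase Rad18 (-0.89) and the histone gene H2ac21 (-0.86). Cdkn2a, which encodes p16 and Arf, had a mean log2 fold change of 0.94 with an adjusted p of 0.0515, or 0.0239 with the pool block, while a second Cdkn2a probe rose by 0.94 with an adjusted p of 0.0238 and another stood at 0.76 (adjusted p = 0.108, 0.0176 with the pool block). Second probes of Kcnj15 (0.63, adjusted p = 0.139, 0.0460 with the pool block) and Lynx1 (0.58, adjusted p = 0.0759) did not pass without a block.

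Of 30 tested G2 and mitosis genes 13 fell over all probes (28 with the pool block) and 29 adjusted over the list alone (median -0.67, camera adjusted p = 3.15e-28, a call lost at 0.130 with an estimated correlation), including the kinases Aurka (-0.69), Aurkb (-0.70) and Cdk1 (-0.63). Of 33 G1/S and replication genes 9 fell over all probes (23 with the pool block) and 32 adjusted over the list alone (median -0.53, adjusted p = 2.49e-25, also lost at 0.130 with an estimated correlation), including Tk1 (-0.70), Mcm5 (-0.60) and Lig1 (-0.56, though -0.48 at an adjusted p of 0.0876 by a second probe). PRC2 subunits fell (median -0.28, 8 of 8 lower, adjusted p = 1.22e-04, 0.0284 with an estimated correlation), 1 over all probes, Phf19 (-0.69). Targets of p53 rose (median 0.24, 22 of 25 higher, adjusted p = 4.94e-06, 0.0231 with an estimated correlation), 2 over all probes, Sesn2 (0.49) and Dcxr (0.55, with a second probe at 0.41 and an adjusted p of 0.136). Adjusted over the list alone 12 p53 targets rose, such as Trp53inp1 (0.50), and 2 fell, Ckap2 (-0.44) and Tnfrsf10b (-0.25). Over all probes 6 p53 targets rose and 1 fell with the pool block. PRC2 and p53 lost their calls with the pool block and an estimated correlation together (adjusted p = 0.111). Luminal progenitor markers (median 0.19, adjusted p = 0.00193), milk genes (median 0.26, adjusted p = 0.0232) and imprinted genes (median 0.099, adjusted p = 0.0351) rose, each at 0.366 with an estimated correlation. Ltf, Notch3 (0.72), Igf2 and Cdkn1c were their members past the threshold over all probes. Interferon response genes rose (median 0.26, adjusted p = 2.33e-04, 0.503 with an estimated correlation), with Cxcl10 past the threshold over all probes and 7 members with the pool block. Cholesterol synthesis genes fell (median -0.14, adjusted p = 0.0131, 0.539 with an estimated correlation), while fibroblast markers (median 0.46) and mesenchymal genes (median 0.18) rose at an adjusted p of 0.0497 each, 0.535 with an estimated correlation.

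The 13 lists without a call for the mean effect had adjusted p between 0.0919 and 0.940. Polycomb-silenced developmental factors had a median of 0.12 and Hox genes 0.029, of which Hoxb2 (-0.43) fell adjusted over the list alone. Also adjusted over the list alone, the kinase inhibitors Cdkn1c, Cdkn2a and Cdkn1a (0.39) rose. Fzd7 (-0.46), Lrp5 (-0.47), Chac1 (-0.43), Tfrc (-0.53), Dnmt1 (-0.48) and Nsd2 (-0.36) fell adjusted over the list alone. With the pool block Hoxb2 (blocked adjusted p = 0.0298), Fzd7 (0.0159), Chac1 (0.0255), Tfrc (0.0206), Dnmt1 (0.0129) and Nsd2 (0.0472) passed over all probes. A second Tfrc probe (-0.55, blocked adjusted p = 0.0567) and a further Nsd2 probe (-0.27, 0.165) did not pass. Other Nsd2 probes did (0.0306 and 0.0262). By probe the mean effect counted 96 higher and 155 lower, and with the animal pool as a block 368 and 408. Without MaSC control replicate 2 or luminal control replicate 1 it counted 313 and 301 changed probes, and without any 1 of the other 10 arrays between 10 and 116.

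**Figure D3:**
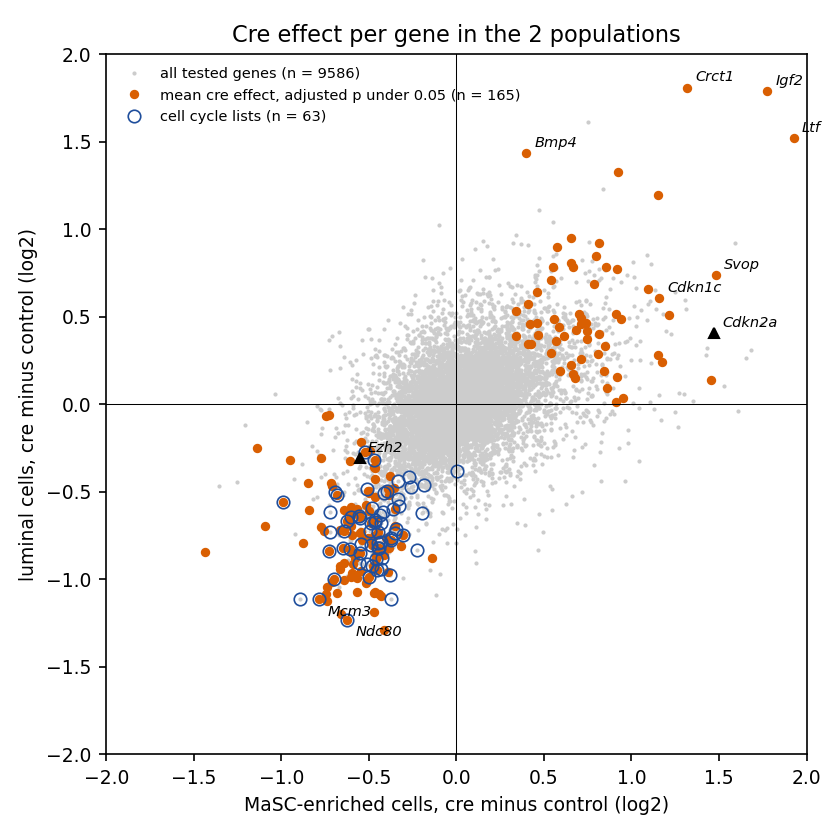
Log2 fold change of cre against control for 9586 genes in MaSC-enriched cells (horizontal axis) and luminal cells (vertical axis), with orange points for the 165 genes whose mean effect passed the threshold, blue rings for the 63 tested cell cycle genes and black triangles for Ezh2 and Cdkn2a. The orange points lie in the upper right (60 genes) and lower left (105 genes) quadrants, which choosing genes by the mean of both effects favours.

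The effects of cre in MaSC and luminal cells, which share no control arrays but come from the same animal pools, had a Pearson correlation of 0.50 and a Spearman correlation of 0.46 across 9586 genes, with 66.1% of genes of the same sign. Genes are not independent replicates, so no p-value was attached. Pool by pool, the correlation lay between 0.24 and 0.34 whether both effects came from 1 pool or from different pools. Crct1 was the gene with a symbol called in both populations, against 0.00188 expected if the calls were independent. Probes ILMN_2476405 (-2.52 in MaSC, -2.15 in luminal cells) and ILMN_2420341 (-1.80 and -1.39), which have no gene symbol, were also called in both. With the pool block 5 genes rose in both (Crct1, Ltf, Kcnj15, Mmp13 and 1700007K13Rik, against 0.111 expected) and 4 fell in both (Ndc80, Oip5, Rad18 and Rad54l, against 0.0995 expected). In luminal cells, second probes of Kcnj15 (blocked adjusted p = 0.0824) and Oip5 (0.0983) did not pass with the block. No probe passed the test of a different cre effect in the populations with limma, and 577 had an unadjusted p under 0.05. The 2 cell cycle lists were the lists called in that test, with luminal minus MaSC medians of -0.32 for G2 and mitosis (27 of 30 lower, camera adjusted p = 5.40e-04) and -0.21 for G1/S and replication (29 of 33 lower, adjusted p = 0.00857). Both calls were lost with an estimated correlation (adjusted p = 0.887 with an estimated correlation). The other 22 lists had adjusted p between 0.123 and 0.974.

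The control arrays of the sorted populations were compared to check the fractions and to describe how they differ. Luminal cells expressed 1936 genes more strongly than MaSC-enriched cells and 1570 more weakly. Highest above MaSC were the casein Csn3 (44.2-fold, log2 fold change 5.47 ± 0.20, adjusted p = 1.17e-08), Gvin1 (27.7-fold), Cadps2 (25.1-fold) and Igsf5 (20.6-fold). They were followed by the iodide transporter Slc5a5 (18.2-fold), the decoy receptor Tnfrsf11b (18.2-fold), the lung surfactant protein Sftpd (17.8-fold), Angptl7 (17.7-fold), Cytip (16.9-fold) and Wnt5b (16.2-fold). Furthest below were the cornified envelope gene Sprr1b (130.4-fold lower, -7.03 ± 0.22, adjusted p = 5.42e-09), Krtdap (123.1-fold lower), Gpx2 (85.9-fold lower) and the basal keratin Krt5 (84.1-fold lower, -6.39 ± 0.40). Next came Dmkn (82.8-fold lower), the keratins Krt90, Krt6b and Krt6a (75.8-, 72.5- and 55.1-fold lower), Vsnl1 (53.8-fold lower) and Trp63, the transcription factor of basal epithelia (51.4-fold lower). All were of 1 sign in 3 of 3 pools.

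Basal and myoepithelial markers were lower in luminal cells (median -1.78 over 32 genes, 23 lower and 1 higher past the threshold, camera adjusted p = 6.35e-12, 0.00134 with an estimated correlation), among them Snai2 (-4.10) and Cdh3 (-1.76). Krt14 was at 0.025 ± 0.15 (adjusted p = 0.916) and a mean log2 signal of 14.1 in both control groups. General luminal keratins and regulators were higher (median 0.47, 12 of 12 higher, 6 of them past the threshold, adjusted p = 0.00153, 0.364 with an estimated correlation), with Cldn3 at 1.90 and Krt18 at 1.30, while Krt8 stood at 0.035 (adjusted p = 0.815). Krt8 and Krt14 were among the brightest probes in both control groups, so that their values near 0 show little. Luminal progenitor and alveolar markers were higher (median 0.89, 11 higher and 3 lower of 20 past the threshold, adjusted p = 0.00731, 0.385 with an estimated correlation), among them Cd14 (2.48) and Lif (2.41). Hormone-sensing markers were higher (median 1.21, 7 higher and 1 lower of 13 past the threshold, adjusted p = 0.0353, 0.477 with an estimated correlation and 0.0546 with the pool block), with Foxa1 at 3.65, but Wnt4 was lower (-3.16). Milk genes were higher (median 1.25, 7 higher and 2 lower of 11 past the threshold, adjusted p = 0.00731, 0.364 with an estimated correlation).

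Cell cycle genes were lower in luminal than in MaSC control arrays, with 24 of 30 G2 and mitosis genes (median -0.91, adjusted p = 8.00e-09) and 24 of 33 G1/S genes (median -0.80, adjusted p = 5.34e-08) past the threshold, both at 0.385 with an estimated correlation. Ezh2 was also lower in luminal control arrays (-0.81 ± 0.19, adjusted p = 0.00612), while Cdkn2a (2.37) and Cdkn2b (1.59) were higher. Interferon response genes were higher (median 0.78, 15 higher and none lower of 31 past the threshold, adjusted p = 1.09e-04, 0.453 with an estimated correlation), and 1 member, Irgm1, had probes that disagreed in sign (-0.41 and 1.93). Lower as groups were Notch pathway genes (median -0.67, 2 higher and 6 lower of 12 past the threshold, adjusted p = 0.0479, 0.364 with an estimated correlation). So were genes of endoplasmic reticulum stress (median -0.36, 2 higher and 8 lower of 24 past the threshold, adjusted p = 0.0318, 0.383 with an estimated correlation) and cholesterol synthesis genes (median -0.62, 1 higher and 11 lower of 18 past the threshold, adjusted p = 9.47e-04, 0.474 with an estimated correlation). The Notch members that differed included the ligands Jag2 (-2.91) and Dll1 (-2.22) and the receptor Notch4 (2.30).

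Among markers of other cell types, all 4 tested endothelial genes were lower in luminal control arrays (median -2.0, Esam at least 2.88-fold and Flt1 at least 4.2-fold lower), with a second Egfl7 probe at 0.26 (adjusted p = 0.341). Adipocyte markers had a median of -1.26 with 4 of 4 lower, 2 of them past the threshold, and of the leukocyte markers H2-Ab1 (at least 2.76-fold) and Coro1a were lower and Ccl5 higher (1.74), while a second H2-Ab1 probe had -0.53 (adjusted p = 0.0811, 0.0398 with the pool block). Fibroblast markers had a median of 0.47 (3 higher and 1 lower of 12 past the threshold, adjusted p = 0.510), with Fbln1 at -5.48 and Col1a1 at 1.603, and 1 of 4 germline genes, Piwil2, was lower past the threshold (at least 5.79-fold). The other lists were not called, with medians of -0.28 for PRC2, 0.036 for PRC1, -0.42 for kinase inhibitors, 0.75 for Hox genes, 0.040 for Polycomb-silenced developmental factors, and 0.030 for imprinted genes. Medians were -0.17 for p53 targets, 0.53 for mesenchymal genes, -0.43 for Wnt, 0.096 for immediate early, -0.023 for housekeeping and 0.071 for other histone methylation genes. No erythroid gene was among the tested genes. By probe, 3040 were higher and 2712 lower, with the animal pool as a block 3688 and 3292, and without animal pool 2, 1258 and 1080.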

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

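In this part, the tests of dilution by other cells, of a response to Cre and of all splits that part every pair were chosen after the results they weigh had been seen, and the others beforehand. What set the following results apart is a difference between the populations: the cell cycle lists fell further with cre in luminal than in MaSC-enriched cells. For G2 and mitosis genes, the difference had a median log2 value of -0.32 and a camera adjusted p of 0.000540, and for G1/S and replication genes -0.21 and 0.00857. The calls were lost with an estimated correlation (adjusted p = 0.887 with an estimated correlation), and fry gave 0.955. By animal pool the medians of the G2 difference were -0.037, -0.43 and -0.49, so pool 1 contributed little to it.

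The wider pattern is that cell cycle lists were lower with cre in both populations, with calls lost with an estimated correlation (adjusted p = 0.209 in MaSC, 0.0907 and 0.0988 in luminal cells). Between-array normalization is argued against, since the highest of the 4 list medians under median scaling and cyclic loess was -0.43, as is an effect of 1 animal pool, since the highest of the 12 medians by pool was -0.34. Fibroblast markers (medians 0.57 and 0.37) and 3 leukocyte markers (0.44 and 0.37) were higher with cre. Dilution by such cells as the whole cause is argued against in luminal cells. There the lower quartile of the general luminal list was -0.18 against -0.63 for the higher cell cycle median, over 12 genes that include the very bright Krt8. In MaSC dilution stays open. The lower quartile of the basal list lay 0.256 above the cell cycle medians, over 32 genes. That list shares Vim and Snai2 with the mesenchymal list, which alone are too few to hold up its lower quartile. Whether the cells behind the higher fibroblast markers express further members of the list was not tested. A response to Cre activity or DNA damage stays open: p53 targets other than the kinase inhibitors rose in both populations, with a larger camera adjusted p of 0.000489 (medians 0.28 and 0.24 over 24 genes, 0.0352 and 0.0667 with an estimated correlation). Excision of Ezh2 may equally lower these genes, and since none of the 12 arrays holds cre-infected cells without floxed alleles it stays open as an untested biological explanation.

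Cre labels were also reassigned within each population. In MaSC the real split gave 19 changed probes and the highest of the other splits 0, 1 of 10 splits giving as many, and 10 splits are too few for a share under 0.05. In luminal cells the real split gave 7 and the highest other 98, 2 of 10 splits giving as many, again too few for a share under 0.05. The split with 98 parted control and cre arrays in 1 pool only and set both arrays of pool 1 against both of pool 3. The second principal component placed these pools apart, at 27.0 and 24.0 for pool 1 and -30.5 and -33.5 for pool 3. With the pool block the real labels gave 99, but the other splits were not run with the block. Among the 4 splits that part all 3 pools, the real one was highest and the others gave 0. For the mean effect the real labels gave 251, and of 100 splits drawn from 200 the highest other gave 68, so 1 of 100 was as large. Only 18 of the 100, the real one included, part all 6 pairs, so this share does not exclude chance. Because control and cre arrays of a pool are paired, all 32 splits that part the 6 pairs were also run. The highest other gave 0, so 1 of 32 was as large, a share of 0.0312 and the smallest that 32 splits can give. For the difference of effects all 10 splits gave 0, and for luminal against MaSC control arrays the real split gave 5752 and the highest other 0, 1 of 10, with too few splits for a share under 0.05 in either.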

How the results depend on the processing

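Fits with the pool block and array quality weights together, and the agreement of effects with a pool left out, were added after the data had been seen, and the cause of the shifts below was not tested unless stated. Ezh2 stayed below 0 in both populations under every alternative run (-0.34 to -0.69 in MaSC, adjusted p 0.0592 to 0.914, and -0.064 to -0.53 in luminal cells, adjusted p 0.141 to 0.999). No probe passed the test of a different cre effect under any alternative run for it. Luminal against MaSC control arrays kept between 4076 and 7109 changed probes (5752 in the reported fit), except 2338 without animal pool 2. With 1 array or pool left out it ranged from 2338 to 5768. Pairing moved the counts of all 3 cre comparisons: of 19 (MaSC), 7 (luminal) and 251 (mean effect) changed probes, the animal pool as a block gave 144, 99 and 776, as a random block 141, 88 and 727, by population 634, 218 and 1649, and with array quality weights 371, 154 and 1128. Array quality weights alone gave 42, 230 and 757, and an intensity trend gave 20 in luminal cells and 385 for the mean. An adjusted p under 0.10 gave 73 in MaSC and 580 for the mean, by its own construction. In MaSC, normexp with offset 50 gave 45, neqc with offset 50 gave 49, median scaling 4, no filter on dim probes 8, detection on all 3 arrays of a group 38 and probes averaged per gene 35. Without a filter the mean effect gave 112, where more probes were tested. The share of increases among the MaSC calls was 63.2% as reported, 86.7% and 83.7% with offset 50 (normexp, neqc), 50% under median scaling and 80.0% under cyclic loess, while no scaling moved the median of all probes by over 0.1. With only the groups compared, on fewer arrays, 1 probe changed in MaSC and 2 in luminal cells. Leaving out 1 array gave 1 to 10 in MaSC, 3 to 66 in luminal cells, the highest without luminal control replicate 1, and 10 to 313 for the mean, the lowest without MaSC control replicate 3. Leaving out 1 pool, and so 4 arrays, gave 0 to 1, 0 to 1 and 1 to 3. The correlation of the MaSC and luminal effects was 0.50, 0.36 without a filter and 0.40 to 0.46 without a pool. Irgm1 in luminal against MaSC control arrays reversed from -0.41 to 0.76 with probes averaged per gene, since its probes disagree. Of 13 named MaSC genes, 13 stayed called with the pool block, 10 under cyclic loess, 8 with an intensity trend, 6 without a filter, 2 under median scaling, 0 with only the groups compared, 0 to 3 with 1 array and 0 with 1 pool left out. Of 5 named luminal genes, 5 stayed with the pool block, 1 with only the groups compared, 2 to 5 with 1 array and 0 with 1 pool left out. Of 31 named genes of the mean effect, 31 stayed with the pool block, 29 under median scaling, 21 without a filter, 4 to 30 with 1 array left out (4 without MaSC control replicate 3) and 0 to 1 with 1 pool left out. Among list tests, 541 cases had the same outcome as reported, most of them without a call in either fit. A call was gained in 6 cases and lost in 53, nearly all with an estimated correlation or fry. The lists called fell with an estimated correlation from 10 to 2 in MaSC, 6 to 0 in luminal cells and 11 to 2 for the mean effect. They fell from 2 to 0 for the difference of effects and from 11 to 1 for luminal against MaSC. Fits to the compared groups alone do not apply to the mean effect and the difference of effects, and the pool by population does not apply to luminal against MaSC. The pool block together with array quality weights was not run for the difference of effects or for luminal against MaSC. Ezh1 had no tested probe. Probes near background limit the folds, which are bounds there.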

Other observations

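In this part, the epidermal differentiation complex was singled out after its genes had been seen among those called, and the tests of MaSC-like basal cells and of the MaSC arrays alone were chosen after the results they weigh. The complex is a cluster of genes for the outer layers of skin, with the S100 genes at its ends, and 20 of its genes were tested. With cre, 19 of 20 were higher in MaSC (median log2 fold change 0.51) and 15 of 20 in luminal cells (median 0.19), where 3 of the 20 were not above background on any array. Passing the threshold were Crct1 and Sprr1a in MaSC and Crct1 in luminal cells, and with the pool block 6 genes in MaSC, among them Ivl (1.43), S100a9 (1.35), S100a8 (1.14) and S100a1 (0.70). For the mean effect the median was 0.37, and 2 genes passed, or 7 with the pool block. In control arrays the complex was lower in luminal than in MaSC cells (median -0.75, 15 of 20 lower, with 2 higher and 10 lower past the threshold).

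The rise of this cluster is a hypothesis found and tested on the same data. MaSC-like basal cells among the sorted luminal cells stay open. The upper quartile of the basal list in luminal cre arrays was 0.111, below the median of the complex there (0.191). This gap decides nothing, since its rule was set after the values were seen. The rise of the complex in luminal cells also had a camera p of 0.201 with an estimated correlation. Basal or skin cells more widely cannot be told apart from a rise within luminal cells: Krt14 stood at 0.217 ± 0.15 and Krt5 at -0.32 ± 0.40, but Krt14 is near the top of the signal range in both populations and Krt5 lay within 2 standard errors of the median of the complex. A run of neighbouring genes that happen to move together cannot be told apart either: 0 of 9144 windows of 20 neighbouring tested genes elsewhere had as high a median of the mean effect, but the complex was picked for its called genes, so the bound of under 1% set for this test decides nothing. Derepression after loss of Ezh2 may raise such genes, which was not tested.

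A further hypothesis was that cre arrays lie further towards the luminal side of the population difference. With the population difference taken from the other pools, the correlation across genes with the cre effect of the left-out pool was 0.0562 at the lowest of 6 and 0.250 at the highest. No control array entered both sides of a correlation, so shared control arrays do not account for these values. All 6 lay above the limit of 0.05 set beforehand, the lowest only just. Without 1039 genes that follow the cell cycle lists the mean of the 6 was 0.121 (SD 0.077). It also lay above its limit of 0.05, but by less than its SD. Cell cycle genes alone therefore cannot be told apart from a shift over both populations. For the MaSC arrays alone the correlations lay between 0.165 and 0.250, with a mean of 0.195 (SD 0.048) and, without the cell cycle genes, 0.173 (SD 0.051). The rule for the MaSC arrays was set after these values were seen, and their reference differences share pools. It therefore does not decide between cell cycle genes alone and a shift. The values may reflect a partial shift of MaSC towards luminal expression, but the call of the luminal progenitor list (median 0.43) was lost with an estimated correlation (adjusted p = 0.209 with an estimated correlation), and general luminal genes (median 0.033) and basal markers (-0.041) had no call.

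Among probes without a gene symbol, ILMN_2476405 fell with cre by 2.52 on the log2 scale in MaSC (SE 0.15, adjusted p = 3.29e-05) and by 2.15 in luminal cells (adjusted p = 1.94e-04), from a mean of 13.7 in MaSC control arrays, in 3 of 3 pools of each. ILMN_2420341 fell by 1.80 (adjusted p = 0.0122) and 1.39 (adjusted p = 0.0430). ILMN_2661588 rose by 0.97 in MaSC (adjusted p = 0.0497). What these probes measure is not given in the sources used here.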
